A study of Mus musculus with 19 samples.

How the data were processed

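Bulk polyadenylated RNA was sequenced from 19 lymphomas of Eμ-Myc mice, a transgenic strain in which the immunoglobulin heavy chain enhancer drives the Myc oncogene in B cells. Per the labels, the mice were wild type for Bptf or carried 1 deleted allele (Bptf+/Δ), and each tumour was classed as early or late onset, with the age at onset in weeks. Which exons the deleted allele lacks was not given in the sources used here. Each library was a separate tumour, and the replicate numbers used below only name libraries in accession order, so no tumours were paired. Per the labels' protocols, libraries were made with a TruSeq kit and sequenced on a Genome Analyzer IIx, with a number of amplification cycles that depended on the protocol version. The version of each library was not given in the sources used here, so no within-batch values could be computed.

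Per the submitters' processing notes, FastQC 0.11.5, TopHat2 2.1.1, Cufflinks 2.2.1, Cuffnorm and Cuffdiff were used with mouse builds GRCm38 and mm10. Which tool made the expression table, the strand setting and the gene annotation were not given in the sources used here. The deposited table held a normalised signal for 21086 genes in each library, which the authors obtained by dividing gene counts by 1 factor per library. All values (100%) were whole multiples of the value of 1 read within 0.01 reads, so whole reads were recovered, and size factors recomputed with DESeq2 equalled the deposited ones. The authors also deposited a log2 fold change and an adjusted p-value for each of 5 comparisons, by a tool not given in the sources used here. Values from them are named below as the authors' deposited table. Symbols of 16109 genes were found in GENCODE M21 (GRCm38), from which coordinates were taken, and 23 symbols had been turned into dates by spreadsheet software and were left as they stood.

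The recovered depth was 8297856 to 12497732 reads per library. Amplified reads without molecular identifiers are not independent molecules, so depth gives a lower limit of the error only. Among all 171 pairs of libraries the lowest chi-square per gene was 19.3, so no 2 libraries agreed within sampling noise. As that noise is only a lower limit, this shows no more than that no library repeats the counts of another. Each library was counted as 1 replicate because it was a separate tumour.

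The design fixed before the data were examined assumed FPKM values, and it was kept as written for this signal. Values were analysed as log2(value + 1) with limma 3.58.1 (trend, empirical Bayes) in R 4.3.3, after keeping the 19927 genes with a value of at least 1 in at least 4 libraries. All fold changes are on that scale, which understates changes of weakly expressed genes. The 4 group means were fitted together in 1 model of 19 libraries, without covariates. The comparisons were genotype averaged over onset, genotype in early and in late tumours, onset averaged over genotype, onset in each genotype, and their interaction. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called changed. Bptf and Myc were also tested with exact two-sided permutation tests in SciPy 1.17.1, with pandas 2.3.3 and NumPy 2.4.6.

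Genes were named by a rule fixed before the data were examined. It took Bptf and Myc, the 10 largest called changes in each direction, the 5 smallest p-values in a direction with fewer than 5 calls, and up to 4 members with the smallest p of each gene list described. Predicted genes and those under a group mean of 2 were passed over, and 1 gene that the rule took is not reported here. The 26 gene lists, fixed at the same time, covered MYC targets, proliferation, p53 targets, B cell stages, other cell types, signalling, metabolism, chromatin remodelling, cooperating loci and Y-linked genes. Each was tested with camera, two-sided, with an estimated correlation between genes and adjustment over the 26 lists. Camera with a preset correlation of 0.01 and fry served as alternatives. Which list and comparison pairs to describe was decided after the list results were seen. Adjustment over a list alone, used below for single members, does not cover this choice.

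Limma, edgeR 4.0.16, DESeq2 1.42.0 and camera were tested on simulated counts with 2-fold, 4-fold and 8-fold changes in 67, 67 and 66 genes. For onset averaged over genotype, limma recovered 16.4%, 46.3% and 75.8% of them and called 6 unchanged genes, against 46 unchanged genes called by DESeq2 and 3 by edgeR. Alternatives fixed before the data were examined changed the pseudocount to 0.1, removed the filter, applied quantile normalisation or array weights, added the Y-linked mean or a score of non-tumour cells (the mean z score of the T cell, macrophage, stromal and endothelial lists) as a covariate, used log2 weeks of onset, fitted only the 2 groups compared, and left out each library in turn. For the MHC class II score, Xist as high or low was also used as a covariate, chosen after seeing the data. Chosen after seeing the data were a filter of 10, edgeR and DESeq2 on the recovered reads, and the fit without the 3 libraries led by a gene other than Eef1a1. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.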

Results

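RNA was measured in 6 early wild-type lymphomas (onset at 9 to 17 weeks), 5 late wild-type lymphomas (28 to 76 weeks), 4 early Bptf+/Δ lymphomas (8 to 13 weeks) and 4 late Bptf+/Δ lymphomas (30 to 66 weeks). Libraries are named WT or HET by genotype, with the onset class and a number. Recovered reads per library ran from 9753478 to 12497732 in WT_early, 8297856 to 11361010 in WT_late, 9770104 to 11546949 in HET_early and 8995949 to 12350345 in HET_late. Eef1a1, a translation elongation factor, was the most abundant transcript in 16 of the 19 libraries. In HET_early_2 it was Col2a1, a cartilage collagen, with 4.36% of reads. In WT_early_6 it was Bpifa2, a salivary protein, with 5.07%, and in HET_late_4 it was Igha, the immunoglobulin A heavy chain, with 5.55%. Xist, transcribed from the inactive X chromosome, was high in 4 of 6 WT_early, 2 of 5 WT_late, 2 of 4 HET_early and 1 of 4 HET_late libraries.

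Bptf, which encodes the largest subunit of the nucleosome remodelling factor NURF, was lower in the Bptf+/Δ tumours (ENSMUSG00000040481.17, GRCm38 chromosome 11, 107033081 to 107132127, minus strand). Its normalised read count was 2041 ± 316.8 (SD, n = 6) in WT_early and 2192.3 ± 341.9 (SD, n = 5) in WT_late tumours. It was 1445.3 ± 123.3 (SD, n = 4) in HET_early and 952.9 ± 510.9 (SD, n = 4) in HET_late tumours. Every Bptf+/Δ library (407.6 to 1573.3) lay below every wild-type library (1664.7 to 2585.7), and an exact permutation test over all tumours gave p = 1.32e-05, the smallest possible. The genotype difference on the log2 scale was -0.49 in early tumours (exact permutation p = 0.00952) and -1.36 in late tumours (exact permutation p = 0.00794, the smallest possible). The difference between these, -0.88, did not pass an exact permutation test (p = 0.0699), and it was -0.53 without HET_late_2. On leaving out 1 library, the late genotype difference ran from -1.66 without HET_late_1 to -1.01 without HET_late_2. Each of these 2 had an exact permutation p of 0.0179, and HET_late_2 was the lowest library at 407.6. In limma's test over all genes Bptf did not pass for genotype averaged over onset (-0.92 ± 0.19 (SE), adjusted p = 0.49), whereas the authors' deposited table gave -0.81 with an adjusted p of 0.0381.

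Myc, the oncogene that drives these tumours, had a normalised read count of 10463.1 in WT_early, 8408.6 in WT_late, 6014.1 in HET_early and 5132.6 in HET_late tumours. The genotype difference, -0.79 on the log2 scale, did not pass an exact permutation test (p = 0.0604), nor did the onset difference of -0.28 (p = 0.529, exact permutation test). The lowest value, 1232.2, was in HET_early_2, and without this library the genotype difference was -0.51 (exact permutation p = 0.156). It passed without WT_late_2 (-0.98, exact permutation p = 0.00562) or HET_early_3 (-0.92, exact permutation p = 0.0355). The onset difference was -0.57 without HET_early_2, -0.45 without WT_late_5, -0.18 without WT_early_2, -0.15 without WT_early_3 and -0.11 without WT_late_2, and did not pass in any of these. Across the 19 tumours, Myc was correlated with the mean of its 46 listed targets in ribosome biogenesis and nucleotide synthesis (Pearson r = 0.86, permutation p = 1e-05, adjusted p = 3e-05 over 3 pairs). Spearman's rho was 0.81 (permutation p = 7e-05, adjusted p = 0.00021), and r was 0.74 without the 2 tumours farthest from the median Myc level. Within wild-type tumours r was 0.86 (n = 11, permutation p = 0.00026, adjusted p = 0.00078), rho was 0.88 (permutation p = 0.00079), and r was again 0.86 without 2 tumours. Within Bptf+/Δ tumours r was 0.88 (n = 8, exact permutation p = 0.0332, adjusted p = 0.0996) and rho was 0.43 (exact permutation p = 0.299). This did not pass after adjustment, and it rested on 2 tumours, HET_early_2 and HET_late_4, without which r was -0.54. Bptf separated by genotype, so a value over both genotypes also holds the genotype difference. Over all, early and late tumours Bptf and Myc were positively related without passing after adjustment (permutation tests, exact for late tumours, adjusted p = 0.149, 0.163 and 0.429 for Pearson's r, and 0.0687, 0.191 and 0.468 for rho, which over all tumours had p = 0.0458 before adjustment). Nor did Bptf and the MYC target mean pass (adjusted p = 0.422, 0.163 and 0.74 for r, and 0.148, 0.191 and 0.644 for rho, by the same permutation tests). Within genotypes, Bptf and Myc had r = 0.05 in wild-type (n = 11, permutation p = 0.884, adjusted p = 0.884, and rho = 0.11 with p = 0.755) and r = 0.18 in Bptf+/Δ tumours (n = 8, exact permutation p = 0.634, adjusted p = 0.634, and rho = 0.45 with p = 0.267). For Bptf and the MYC target mean, r was 0.19 in wild-type (n = 11, permutation p = 0.573, adjusted p = 0.859, and rho = 0.11 with p = 0.755) and -0.25 in Bptf+/Δ tumours (n = 8, exact permutation p = 0.539, adjusted p = 0.634, and rho = -0.38 with p = 0.36). Without the 2 tumours of each genotype farthest from its median Bptf level these 4 values of r were -0.17, -0.1, 0.09 and -0.12.

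**Figure D1:**
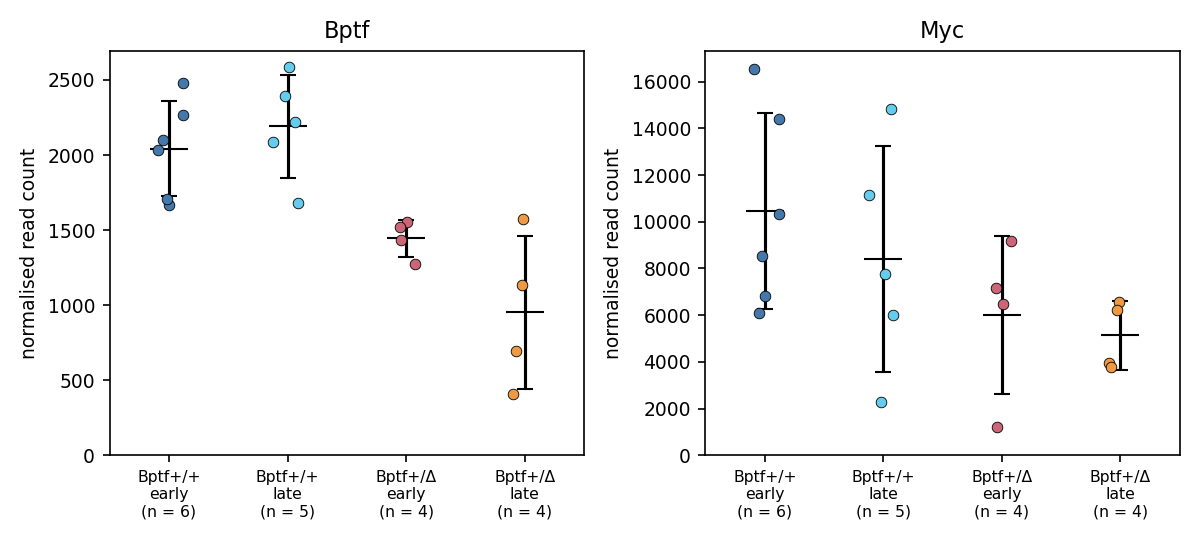
Normalised read counts of Bptf (left) and Myc (right) per tumour, by genotype and onset class, with the mean (horizontal line) and SD (bars). Bptf in the 8 Bptf+/Δ tumours sits between 407.6 and 1573.3, below all 11 wild-type tumours, while the Myc values of the groups overlap.

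Genotype averaged over onset asked what differed between Bptf+/Δ and wild-type lymphomas of either class. Slc25a37, a mitochondrial iron importer, was lower by 1.03 ± 0.24 (SE) on the log2 scale in Bptf+/Δ tumours, and Prkce, a protein kinase C, by 1.24 ± 0.31. Ranbp6 and Pcm1, a centriolar satellite protein, differed by -0.61 ± 0.16 and -0.60 ± 0.16. Mum1l1 (3.26 ± 0.75), Lyplal1 (1.73 ± 0.40), Nav3 (2.37 ± 0.56), Ppt1, a lysosomal thioesterase (0.63 ± 0.15), and Serpinb9, a granzyme B inhibitor (1.14 ± 0.29), were higher. None of these passed, each with an adjusted p of 0.49, and limma called 0 of 19927 genes. At an unadjusted p under 0.05 there were 1988 genes in limma, where chance alone would on average put a share of 0.05 of the 19927. In contrast, edgeR called 0 genes and DESeq2 18, and the authors' deposited table held 55 changed genes.

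By gene list, 45 of 46 MYC targets had lower means in Bptf+/Δ tumours (median -0.33), with examples Mcm4 (-0.76), Utp20 (-0.64) and Mybbp1a (-0.54). All 39 proliferation genes did so as well (median -0.50), among them the kinetochore genes Cenpf (-0.75) and Cenpe (-0.67). The medians were -0.12 and -0.20 without HET_early_2. Of 15 pan-B genes 13 were lower (median -0.96, and -0.30 without HET_early_2), including the B cell transcription factor Pax5 (-1.40) and the kinase Blk (-1.47). In the list of NURF and ISWI subunits, 12 of 14 members were lower (median -0.27), and Bptf and Baz1b (-0.56) passed when adjusted over the list alone. Interferon response genes were higher in 34 of 38 cases (median 0.86), with Igtp at 1.0 and Zbp1 at 1.87. T cell markers were higher in 21 of 23 cases (median 1.33), with Lat at 1.92 and Cd28 at 2.1. All 14 cytotoxic markers (median 1.09, Gzmb 2.03), all 24 macrophage markers (median 0.69, Ccr2 0.81) and all 23 stromal genes (median 0.73, Pdpn 1.31) were higher, with medians of 0.43 for macrophage markers and 0.17 for stromal genes without HET_early_2. Of 29 p53 targets 22 were higher (median 0.40), including Phlda3 (1.51) and Plk2 (1.04). No list passed with an estimated correlation, where the adjusted p was 0.435 for the stromal list, 0.358 for T cell markers and 0.323 for the 8 others. With a preset correlation of 0.01 all 10 passed, and with fry none did. With a score of non-tumour cells, the mean of the T cell, macrophage, stromal and endothelial lists, as a covariate the MYC target median was 0.02.

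In early tumours alone, Rsrp1, encoding an arginine and serine rich protein, was lower in the Bptf+/Δ group by 1.31 ± 0.26 (SE), as were Metap1d (-1.0), Fbxl6 (-0.95), Slc7a6os (-0.81) and the antisense transcript Rab26os (-1.53), whose reads cannot be told from those of Rab26 without strand. Rgs16, a regulator of G protein signalling, was higher by 2.69 ± 0.57, as were Mum1l1 (5.06 ± 1.03), Trpc5 (1.61), Pcdhac1 (3.70) and Pcdh20 (2.12), of which the last 3 had group means under 20 reads. All had adjusted p = 0.392 and none passed. Limma and edgeR called 0 genes, with 2293 at an unadjusted p under 0.05 in limma, whereas DESeq2 called 394 and the authors' deposited table held 304. All 17 immediate early genes, which respond within minutes to stimulation, were higher (median 1.47), and 6 passed when adjusted over the list alone. Egr1 had a mean of 1556.2 ± 2283.9 (SD, n = 4) against 80.0 ± 45.6 (SD, n = 6), and Fosb 465.4 against 19.4. Without HET_early_2 the median was 0.42. All 18 endothelial markers were higher (median 0.96, and 0.56 without HET_early_2), and Eng (1.79), Pecam1 (0.86) and Lyve1 (2.98) passed when adjusted over the list alone. Proliferation genes (39 of 39 lower, median -0.80) and MYC targets (45 of 46 lower, median -0.52), with examples Cdc6 (-1.27) and Gnl3 (-0.98), had medians of -0.17 and -0.14 without HET_early_2. The stromal median of 1.03, with Acta2 at 1.36 and Pdgfra at 1.35, became -0.19. None of these 5 lists passed with an estimated correlation (adjusted p = 0.622 for the stromal list and 0.579 for the rest).

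In late tumours alone, interferon response genes were higher in the Bptf+/Δ group for 37 of 38 members (median 0.94), and 6 passed when adjusted over the list alone. Among them were the interferon-inducible GTPases Igtp (497.2 ± 205.6 against 151.7 ± 93.5, SD, n = 4 and 5) and Irgm1 (734.7 against 422.0), with Zbp1 (2.62) and Ifi27l2a (1.90). All 14 cytotoxic markers had higher means (median 1.36), including Ccl5 (3.04), Gzmb (2.78) and Nkg7 (2.25). Oxidative phosphorylation genes were higher for 35 of 39 members (median 0.36, Uqcrq 0.64), and pro-B and pre-B markers were lower for 22 of 23 (median -1.38), with the recombinase gene Rag1 at -4.95 and Cplx2 at -2.81. None of these lists passed with an estimated correlation (adjusted p = 0.434 for each). Other small p-values belonged to Muc20 (3.49), Klra17 (5.29), Ppt1 (0.97) and Negr1 (3.56), which were higher, and to Usp24 (-0.90), Pip4k2b (-0.85), the sialyltransferase gene St6gal1 (-1.54) and Mnt, a MYC antagonist (-0.72). Their adjusted p-values lay between 0.773 and 0.796. Limma and edgeR called 0 genes, with 1222 at an unadjusted p under 0.05 in limma, while DESeq2 called 33 and the authors' deposited table held 15.

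Onset averaged over genotype asked how late tumours differed from early ones, and it gave 87 changed genes in limma, 49 higher and 38 lower in late tumours. Mice with late tumours were also older, so age and onset class cannot be told apart here. The genes that rose included 3 of 11 members of the MHC class II antigen presentation list. H2-Eb1, a class II beta chain, averaged 1758.7 ± 1020.1 (SD, n = 6) in WT_early and 7742.4 ± 4521.4 (SD, n = 5) in WT_late tumours, and 2108.2 ± 871.0 (SD, n = 4) in HET_early and 9218.4 ± 5313.5 (SD, n = 4) in HET_late tumours (1.99 ± 0.43 (SE), adjusted p = 0.04997). H2-DMa and H2-DMb1, which load peptides onto class II, rose by 2.25 ± 0.41 and 1.78 ± 0.38 on the log2 scale (adjusted p = 0.0406 and 0.0485, chromosome 17, 34119541 to 34139101 and 34153072 to 34160230). All 11 members had positive values (median 1.60), and 8 passed when adjusted over the list alone. Ly6c2, a surface antigen of monocytes and other leukocytes, rose by 4.0 ± 0.86, with a HET_late mean of 8378.6 ± 13351.4 (SD, n = 4) that HET_late_4 dominated at 28318.8. Zcchc18 (3.43), B4galnt4 (3.30), Gpr171 (3.18), Serpini1 (2.40), the glyoxylate reductase gene Grhpr (1.75) and Sla, an adaptor that dampens antigen receptor signalling (1.59), also rose. In a principal component analysis of the 1000 most variable genes, 5 late libraries stood apart on the second component (21.4% of the variance), with HET_late_1, WT_late_1, HET_late_2, HET_late_4 and WT_late_2 at -67.6 to -27.4 and the others at 5.1 or above. These 5 had the highest MHC class II scores (1.23 to 1.94, others -2.04 to 0.79) and the lowest pro-B and pre-B scores (-2.31 to -1.38, others -0.98 to 3.57).

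The genes that fell with late onset included Cd93, a surface marker of early B cells, which fell by 2.54 ± 0.54 (SE) on the log2 scale, from a mean of 2282.3 to 1581.4 in wild-type and from 3886.4 to 271.2 in Bptf+/Δ tumours. Also lower were Plekhh1 (-2.84), Col26a1 (-2.73), Gk5 (-2.64), Fam84b (-2.58), Slfn9 (-2.44), Trio, a guanine nucleotide exchange factor (-2.40), Tmem136 (-2.27) and Rragd, a GTPase of amino acid sensing (-2.22). Of 23 pro-B and pre-B markers 22 had negative values (median -1.97), and 12 passed downwards when adjusted over the list alone, including Rag1 (-5.32), Rag2 (-4.65) and Cplx2 (-3.59), although Cd93 alone passed over all genes and 1 member passed upwards over the list.

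Most members of several further lists had onset differences of 1 sign without passing over all genes. Members of a list can be correlated, so the number passing over a list alone is no test of that list. All 39 oxidative phosphorylation genes had positive values (median 0.45), and 29 passed when adjusted over the list alone, such as Uqcrq (0.76), Ndufb9 (0.66) and Cox8a (0.67). Of 15 BCL2 family genes 12 were positive (median 0.36), and 6 passed when adjusted over the list alone, including Bad (0.84) and Mcl1 (0.63). Of 25 genes of the unfolded protein response 22 were positive (median 0.49), 5 of them passing when adjusted over the list alone, such as Sdf2l1 (1.01) and Pdia6 (0.79). Germinal centre and plasma cell markers were positive in 17 of 19 cases (median 1.49), with Derl3 (2.56) and Rgs13 (4.42) passing when adjusted over the list alone. The scores of this list in WT_late_2 (3.6) and HET_late_4 (3.65) lay far above those of the other late tumours (-1.15 to 0.11 in WT_late and 0.35 to 0.73 in HET_late). Endothelial markers were negative in 15 of 18 cases (median -0.64, and -0.40 without HET_early_2), and Kdr (-1.33), Cdh5 (-1.14), Robo4 (-1.01) and Tie1 (-0.89) were among 5 passing when adjusted over the list alone. T cell markers had a median of 0.74, and Cd8b1 (3.44) alone passed when adjusted over the list alone. The median was 0.17 for macrophage markers, where Ly6c2 alone passed and C1qb was at 0.86, and -0.83 for stromal genes (Pdgfrb -0.83). Without HET_early_2 these were 0.43 and -0.20. With an estimated correlation no list passed over the 26 lists, with adjusted p = 0.265 for MHC class II, oxidative phosphorylation and the BCL2 family. It was 0.423 for pro-B, plasma cell and unfolded protein lists, 0.454 for endothelial and 0.639 for T cell markers, and 0.727 for macrophage markers and stromal genes. Fry passed the MHC class II, oxidative phosphorylation and BCL2 lists, each with an adjusted p of 0.022. The 87 calls lay close to the threshold: none remained with the Y-linked mean as a covariate (smallest adjusted p = 0.0705) or without the 3 libraries led by another gene (0.0606). None remained either in 10 of the 19 fits that left out 1 library, while edgeR called 539 genes and DESeq2 1851.

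**Figure D2:**
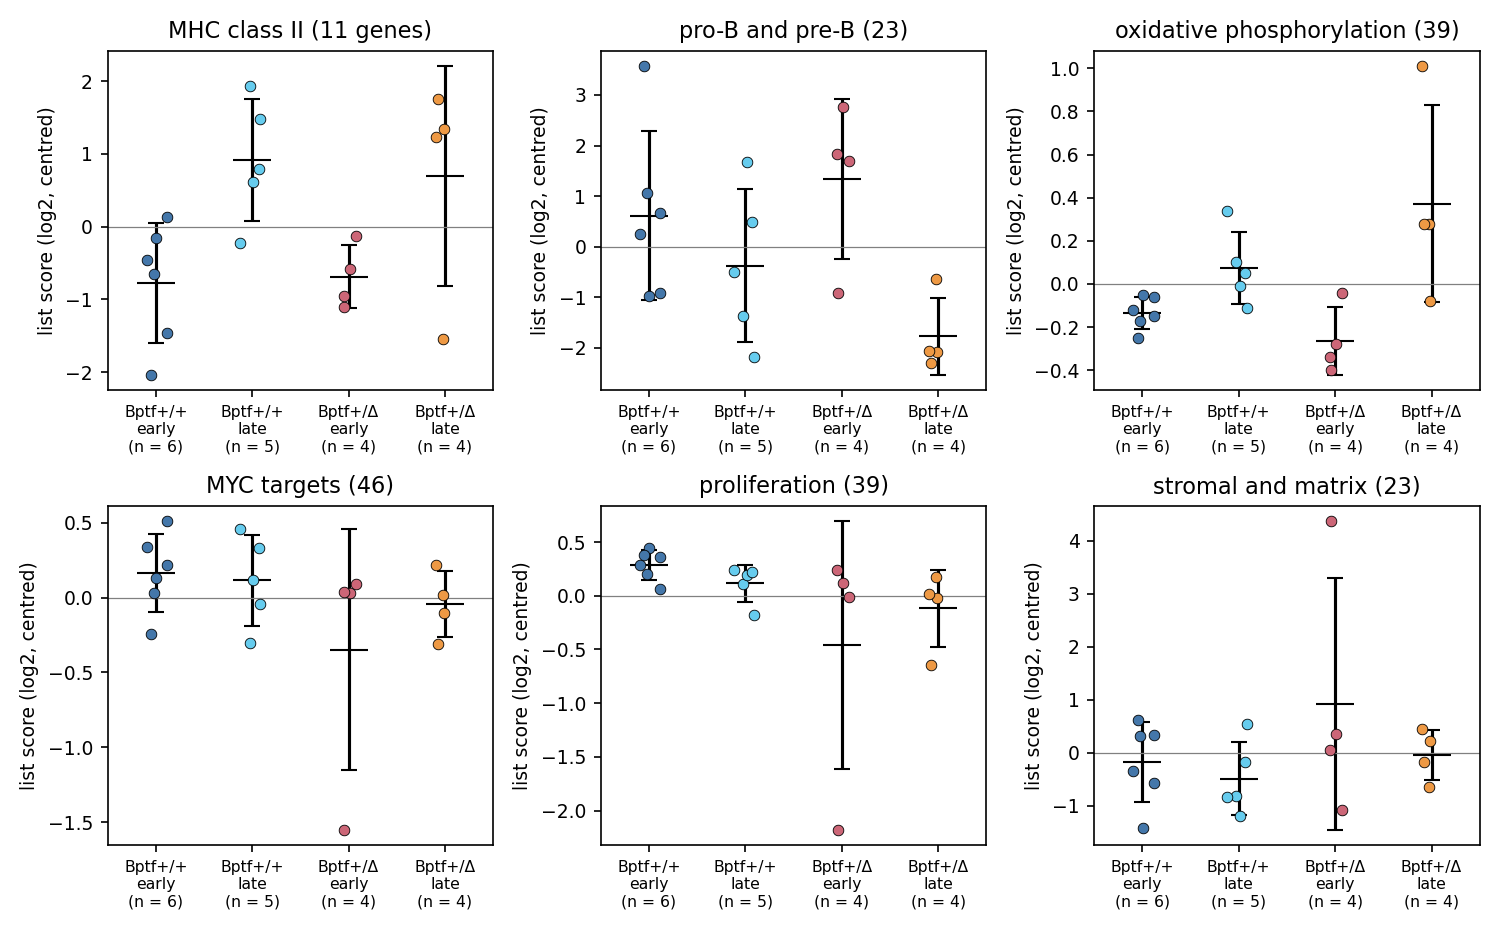
Mean log2 level of 6 gene lists per tumour, centred on the 19 tumours, by genotype and onset class, with the mean (horizontal line) and SD (bars). HET_late_3 lies at -1.54 for MHC class II, below the 3 other HET_late tumours at 1.23 to 1.76, and HET_early_2 is the low point at -1.55 for MYC targets and -2.18 for proliferation.

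Within wild-type tumours, all 11 MHC class II genes were higher in late tumours (median 1.85), and 8 passed when adjusted over the list alone, including H2-DMa (2.25 ± 0.53 (SE)), H2-Eb1 (2.15) and H2-Aa (1.96). BCL2 family genes were higher in 14 of 15 cases (median 0.35), with Bad at 0.70 and Bmf at 1.01, none passing when adjusted over the list alone. With an estimated correlation both lists had an adjusted p of 0.102. Hoxb6 (2.96), Evl (1.09), Adamts13 (1.83) and Gpr171 (3.04) were higher, and Plekhh1 (-2.93), Ppm1e (-2.12), the cytokine signalling suppressor Socs2 (-2.72), the meiotic methyltransferase gene Prdm9 (-1.57) and Ccnl2 (-0.69) were lower. None passed (adjusted p = 0.841), and limma and edgeR called 0 genes, with 966 at an unadjusted p under 0.05 in limma. These 966 were fewer than a share of 0.05 of the 19927 genes tested. DESeq2 called 121, and the authors' deposited table held 259.

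Within Bptf+/Δ tumours, pro-B and pre-B markers were lower in late tumours for 22 of 23 members (median -3.03), and 10 passed when adjusted over the list alone, including Cd93 (-3.87), Rag1 (-7.61) and Gfra1 (-6.13). All 39 oxidative phosphorylation genes were higher (median 0.66), 31 of them passing when adjusted over the list alone, with Uqcrq at 1.11 and Cox8a at 0.99. All 11 MHC class II genes were higher (median 1.58), and 5 passed when adjusted over the list alone, H2-DMa at 2.24. All 18 endothelial markers were lower (median -1.29, and -0.67 without HET_early_2), with 6 passing when adjusted over the list alone, Kdr at -1.93 and Eng at -1.88. Immediate early genes had a median of -0.96, with Fosb at -3.88 and Egr1 at -3.33 among 3 passing downwards and Jund at 1.22 passing upwards when adjusted over the list alone, and the median became 0.06 without HET_early_2. None of these lists passed with an estimated correlation (adjusted p = 0.533, and 0.703 for immediate early genes), while fry passed the endothelial and oxidative phosphorylation lists (adjusted p = 0.0485 for each). Single genes came close to the threshold, with adjusted p = 0.0527 for Ssbp4 (1.25 ± 0.20 (SE)), Spcs2 (1.36), Jtb (1.15), Mrpl57 (1.45), Pmm1 (1.31), Col26a1 (-4.50), Col27a1 (-6.89), Slfn9 (-3.67), Pcdh17 (-2.99) and Hivep2 (-1.96). Limma and edgeR called 0 genes, with 3887 at an unadjusted p under 0.05 in limma, while DESeq2 called 1721 and the authors' deposited table held 621. The median of all genes shifted by -0.12 in this comparison and by 0.04 after quantile normalisation, which gave 59 calls.

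The interaction asked whether the onset difference depended on genotype. Rsrp1 had the smallest p, with an onset difference that was 1.92 ± 0.37 (SE) larger in Bptf+/Δ tumours (adjusted p = 0.436). Metap1d (1.43), Jtb (1.13), Snhg20 (2.03) and Cenpv (3.0) had positive values, and Loxhd1 (-3.18), Elk3 (-2.94), Trpc5 (-2.37), Draxin (-5.11) and Plb1 (-4.54) negative ones. Limma and edgeR called 0 genes, with 1382 at an unadjusted p under 0.05 in limma, and DESeq2 called 96. Over 19927 genes, which are not independent replicates, the onset fold changes of the 2 genotypes had a Pearson r of 0.336. The genotype fold changes of the 2 onset classes had an r of 0.099. Limma called no gene in both members of either pair. With DESeq2, 37 genes were higher in late tumours of both genotypes against 5.87 expected if genes were independent, and 9 were lower against 1.97. As genes are not independent, these expected counts are no test of the overlap. For the genotype fold changes DESeq2 shared 0 genes against 0.47 higher and 0.05 lower expected.

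Some libraries had shifted levels over a whole chromosome. Medians over the genes of a chromosome, from 9018 genes with a mean of at least 100, relative to the other libraries, differed from 0 by 0.25 or more on the log2 scale in 20 of 380 library and chromosome pairs, in 10 libraries. Of these, 19 were upward, and the 1 downward shift was chromosome 13 in WT_early_3 (-0.63). Chromosome 15, which carries Myc, was shifted by 0.53 in WT_late_5, 0.38 in WT_late_1, 0.36 in WT_early_5 and 0.27 in HET_late_1. No other pair exceeded 0.22.

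**Figure D3:**
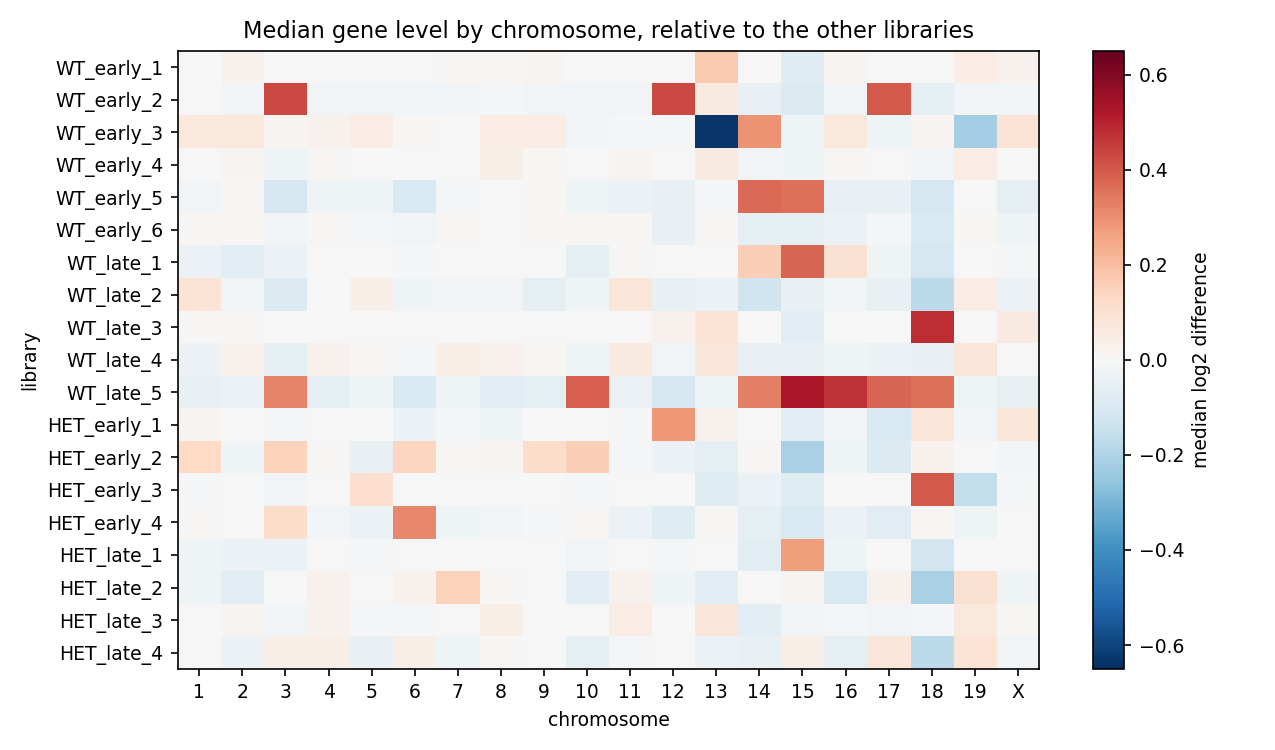
Median log2 difference of the genes of each chromosome (columns) in each library (lines of cells) from the other libraries, in colour from blue (lower) to red (higher). WT_late_5 has 7 chromosomes shifted upward, and WT_early_3 has chromosome 13 at -0.63.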

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

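The cartilage, read depth and macrophage tests below, the values by Xist level, the tests of shifts by genotype and onset, and the size of shift that counted for a chromosome, were chosen only after the result was seen. Chance marks about 1 in 20 groups as holding a stray sample, and 13 of 192 combinations of group and measure were so marked.

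HET_early_2 stood apart from the 3 other HET_early tumours, with the lowest score of MYC targets (-1.55, others 0.03 to 0.09), proliferation (-2.18, others -0.01 to 0.24) and pan-B genes (-3.37, others 0.25 to 0.7). Cells of another tissue in the sample may account for this, since its mean log2 level of 14 cartilage genes was 14.27 and lay 5.77 above the next library, with Col2a1 at 566684.6 and Acan at 142976.8. Muscle genes were high as well, with Acta1 at 92595.6 and Ckm at 22901.7. A shallower library cannot be told apart as a contributor by its depth of 9770104 reads (9.77 in units of 1e6), which was neither the lowest of the 19 nor at the median. No biological explanation was tested.

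In HET_late tumours HET_late_3 had the lowest H2-DMa (343.8, others 1921.1 to 2375), H2-Eb1 (1578.8, others 9726.5 to 13354.6) and MHC class II score (-1.54, others 1.23 to 1.76), against the higher mean of class II genes in late tumours. That higher mean was not general, since WT_late_4, at -0.23, also lay within the early range of -2.04 to 0.13. The class II list did not pass with an estimated correlation. The mean rise was 1.54 ± 0.44 (SE) for the list score. If more macrophages alone were the source, a macrophage score was predicted to rise at least as much. Such a score, here and for dendritic cells, follows the amount of cells and cannot address the class II level per cell. Without Ly6c2, which passed upwards, the 23 macrophage markers rose by 0.23 ± 0.29 (SE), and the class II rise exceeded this by 1.3 ± 0.42 (SE). With Ly6c2 the macrophage score went from -0.46 to -0.12 in wild-type and from 0.2 to 0.64 in Bptf+/Δ tumours, and the excess over it was not tested. Over dendritic cell markers the excess was 1.13 ± 0.55 (SE), only just past the bound of 2 standard errors. The other genes of chromosome 17 had a median onset difference of 0.09, under the 0.3 that a gain of this chromosome was set to need. The values argue against the sex of the mice as the whole cause, since the score rose by 1.61 ± 0.46 (SE) with the Y-linked mean as a covariate and by 1.56 ± 0.47 (SE) with the Xist level as high or low. It went from -0.94 ± 0.7 (SD, n = 6) to 1.36 ± 0.57 (SD, n = 3) in libraries with high Xist and from -0.44 ± 0.55 (SD, n = 4) to 0.55 ± 1.25 (SD, n = 6) in those with low Xist, where the spread was wide. With the Y-linked covariate H2-DMa went from 2.25 ± 0.41 to 2.27 ± 0.43 (SE), and its call in limma ended at an adjusted p of 0.0705, not with a smaller fold. Its unadjusted limma p went from 2.58e-05 to 5.25e-05. In the main fit H2-Eb1 passed at an unadjusted limma p of 0.000196, so the adjustment over all genes also bore on the lost call. A difference in onset class of the tumour cells themselves remains a hypothesis. The relation of this score to pro-B markers bears on it (r = -0.66 over all tumours and -0.55 within groups). Without WT_early_5 and WT_late_3 the latter was -0.43, with a permutation p of 0.0656. The unassigned protocol versions may also contribute and were not tested. Early and late tumours also differed in the age of the mice at onset (8 to 17 against 28 to 76 weeks). Age therefore cannot be told apart from onset class in these tumours.

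The chromosome-wide shifts may reflect gain or loss of chromosomes in the tumours. In 20 of 20 shifted pairs the proximal and distal parts of the chromosome shifted the same way by 0.15 or more. A few strongly changed genes were predicted to leave under 60% of the genes of a chromosome on the shifted side, and the lowest share was 70.1%. The pairs were chosen by their median over the same genes, which favours a shift in both parts and puts most genes on that side. Neither the shift of both parts nor this share is therefore an independent test. The parts show only that no shift was confined to 1 of them. Random gene sets of the same size gave medians of at most 0.11. There were 7 in WT_early, 9 in WT_late (7 of them in WT_late_5), 3 in HET_early and 1 in HET_late tumours, and exact permutation tests of shifts per library did not pass for genotype (-0.95 for Bptf+/Δ less wild type, p = 0.319, and -0.4 with p = 0.449 without WT_late_5) or onset (0.11 for late less early, p = 0.935, and -0.62 with p = 0.194 without WT_late_5). A difference by group therefore stays open, and no DNA data were used here.

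Other single values that stood apart were the HET_late_3 score of pro-B and pre-B markers (-0.64, others -2.31 to -2.07) and its Col26a1 count of 1.6, where the others had 0. Rragd was highest in HET_late_4 (54.2, others 18.7 to 22). The germinal centre and plasma cell score was highest in WT_late_2 (3.6, others -1.15 to 0.11) and in HET_late_4 (3.65, others 0.35 to 0.73). WT_late_1 had the lowest pan-B score (-1.23, others 0.43 to 0.66) and the highest erythroid score (2.74, others -1 to -0.1). Y-linked reads above the limit of 3 reads occurred in 2 libraries with high Xist, with 5 Ddx3y reads in WT_early_4, and 14 Ddx3y, 4 Eif2s3y and 6 Kdm5d reads in WT_early_5.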

How the results depend on the processing

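The filter of 10, edgeR, DESeq2 and the fit without the 3 libraries led by another gene were chosen only after the result was seen, and the cause of each difference was not tested. No paired analysis was possible because replicate numbers only follow accession order and tie no tumours together. For onset averaged over genotype the 87 calls became 667 with array weights, 0 with the Y-linked mean, 519 with the non-tumour score, 8 with log2 weeks, 206 with a filter of 10, 0 without the 3 libraries, 539 with edgeR and 1851 with DESeq2. The pseudocount of 0.1, no filter and quantile normalisation gave 73, 73 and 62 calls. Leaving out 1 library gave 0 to 490 calls. None remained without WT_early_1, WT_early_3, WT_early_4, WT_early_5, WT_early_6, WT_late_1, WT_late_4, HET_early_1, HET_early_4 or HET_late_2. Without WT_late_2, WT_early_2, HET_late_4, HET_early_2, WT_late_3, HET_late_1 and HET_late_3 there were 13, 15, 17, 162, 284, 342 and 490. Of the 20 genes the rule took here, none changed direction in any alternative, and 20 stayed past the threshold with array weights, the non-tumour score, a filter of 10 and DESeq2, 19 with edgeR, 1 with log2 weeks and 0 with the Y-linked mean or without the 3 libraries.

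For onset in Bptf+/Δ tumours, where the main count was 0, quantile normalisation gave 59, array weights 191, the non-tumour score 150, only the 2 groups compared 21, a filter of 10 68, DESeq2 1721 and DESeq2 with only the 2 groups 700. Leaving out 1 library gave 0 to 257, with 257, 213, 92, 57, 52, 15 and 5 without HET_late_3, HET_late_1, WT_late_3, HET_early_3, WT_late_1, WT_early_5 and WT_late_2. For genotype in early tumours array weights gave 110 calls, DESeq2 394 and DESeq2 with only the 2 groups 333, and leaving out 1 library gave 0 to 2 (2 without WT_late_3). Genotype in late tumours gave 33 and 13 with the same DESeq2 fits, and 0 to 2 on leaving out 1 library (2 without HET_late_3). DESeq2 also called 18 genes for genotype averaged over onset, 96 for the interaction and, for onset in wild-type tumours, 121 or 267 with only the 2 groups. All other alternatives here gave 0. Fold changes of DESeq2 with only the 2 groups matched the authors' deposited table with r = 0.99999 in 3 comparisons and 0.97474 for onset in Bptf+/Δ tumours, with 301 of 304, 13 of 15, 254 of 259 and 458 of 621 of the authors' genes shared.

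Bptf stayed lower in Bptf+/Δ tumours throughout. Its early difference had an unadjusted p under 0.05 with array weights (-0.473), with only the 2 groups compared (-0.487) and with DESeq2 on these groups (-0.498), and leaving out 1 library gave -0.543 to -0.428. The onset difference of Myc in Bptf+/Δ tumours, 0.055, turned negative with quantile normalisation (-0.029), array weights (-0.472), the non-tumour score (-0.248), edgeR (-0.22), both DESeq2 fits (-0.229) and without the 3 libraries (-0.467), and ran from -0.597 to 0.369 on leaving out 1 library, negative without HET_early_2 (-0.597), HET_late_1 (-0.079) or HET_late_3 (-0.053). Its interaction, 0.53, was -0.223 with array weights and -0.126 to 0.839 on leaving out 1 library, the lowest without HET_early_2. The correlation of genotype fold changes was -0.053 without the 3 libraries. With the non-tumour score the MYC target median for genotype averaged over onset was 0.022. The score holds the T cell, macrophage and stromal lists, so their medians of -0.027, -0.009 and -0.342 (-0.353 for stromal genes in early tumours) and Dcn at -0.038 are uninformative. Without the 3 libraries the early stromal median was -0.095 and the immediate early median for onset in Bptf+/Δ tumours 0.08. On leaving out 1 library they ran from -0.185 to 1.815 and from -1.609 to 0.057, at -0.185 and 0.057 without HET_early_2. Only some fits tested lists. In these the 36 results described failed with an estimated correlation. All passed with a preset correlation of 0.01 and 5 with fry.

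Other splits of the tumours tested chance. For onset averaged over genotype 2 of 100 splits, the real one included, gave 87 calls or more, a share under 0.05 but unadjusted. The highest other split gave 377, which points to a structure of the samples. A real count of 0 is matched by any split, so the 100 splits (35 for onset in Bptf+/Δ tumours) decide nothing for genotype averaged over onset (highest other 199), in early (14) and late tumours (599), for onset in wild-type (1) and Bptf+/Δ tumours (647) and for the interaction (0). With DESeq2 on the 2 groups, 2 of 24 splits reached the real 700 for onset in Bptf+/Δ tumours (highest other 1649) and 2 of 24 the real 333 for genotype in early tumours (highest other 690), so chance was not excluded for either. The fold change correlation of 0.336 was reached by 4 of 100 labellings (highest other 0.461), and that of 0.099 by 20 of 100 (highest other 0.366). At this depth and number of tumours, limma recovered 16.4% of simulated 2-fold onset changes, so most changes of that size were not detectable.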

Other observations

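The test on cartilage of the same tumour sample and the relation of MHC class II to pro-B markers below were chosen only after the result was seen. Cdkn2a, which encodes the tumour suppressors p16 and p19ARF, was at 2231.7 in WT_early_3 and 2011.5 in HET_early_3, and between 8.5 and 610.1 in the 17 others. WT_early_3 also had the lowest Trp53 count, 460.9, against 789.6 to 2839.7 in the other libraries. Genes of the surrogate light chain, which pre-B cells use, were highest in WT_early_5, with Igll1 at 3936.3 and Vpreb1 at 2093.7, followed by HET_early_1 at 1071.8 and 385.5. These genes were chosen after their values were seen.

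Lists not described above did not pass for onset averaged over genotype with an estimated correlation. Their medians were 0.12 for MYC targets (adjusted p = 0.727), 0.12 for proliferation (0.791), 0.10 for p53 targets (0.514), 0.51 for mature B markers (0.639), 0.21 for pan-B identity (0.727), 0.89 for cytotoxic markers (0.639) and -0.71 for neutrophil markers (0.727). They were -0.10 for erythroid markers (0.848), -0.18 for genes of adjoining tissue (0.791), -0.25 for the interferon response (0.957), 0.10 for NF-kB targets (0.727), -0.39 for immediate early genes (0.791) and 0.20 for glycolysis (0.639). They were -0.21 for NURF and ISWI subunits (0.727), -0.25 for known cooperating loci (0.514) and 1.71 for Y-linked genes (0.727). Without HET_early_2 the medians of MYC targets, proliferation and pan-B identity were -0.08, -0.19 and -0.04, and those of p53 targets, mature B and erythroid markers were 0.34, 0.08 and 0.18. They were then -0.37 for genes of adjoining tissue, -0.12 for the interferon response, 0.26 for NF-kB targets, 0.01 for immediate early genes and 0.34 for glycolysis.

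Across the 19 tumours the mean z score of MHC class II genes was negatively related to that of pro-B and pre-B markers, with a Pearson r of -0.66 (permutation p = 0.00238, adjusted p = 0.0143 over 6 relations) and a rho of -0.71 (permutation p = 0.00113, adjusted p = 0.00678). For deviations from the 4 group means r was -0.55 (permutation within groups p = 0.011, adjusted p = 0.033) and rho was -0.63 (p = 0.00802, adjusted p = 0.0241). Without the 2 tumours farthest from the median these values of r were -0.57 (permutation p = 0.0188) and -0.43 (permutation p = 0.0656), so the second rested on WT_early_5 and WT_late_3. In wild-type tumours r was -0.67 (n = 11, permutation p = 0.0221, adjusted p = 0.0442, rho = -0.65 with p = 0.0332 and adjusted p = 0.0664), and it rested on WT_early_5 and WT_late_1, without which it was -0.27. It did not pass in Bptf+/Δ (-0.66, exact permutation p = 0.0787, rho = -0.6 with p = 0.132), early (-0.58, permutation p = 0.0794, rho = -0.54 with p = 0.113) or late tumours (-0.42, exact permutation p = 0.261, rho = -0.68 with p = 0.0503), with adjusted p = 0.0953, 0.0953 and 0.261 for r. Without 2 tumours r was -0.64, -0.34 and -0.77 in these.

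WT_early_5, a library with Xist at 9292.4, held cartilage transcripts at a median of 1.73% of their HET_early_2 level over 14 genes, and 27 Y-linked reads, 1.87% of the HET_early_2 level. A hypothesis was that reads or RNA of HET_early_2 had entered it. It was tested on 38 further genes with at least 2000 in HET_early_2 and at least 1000 times the median of the libraries other than WT_early_5. Their median in WT_early_5 was 0.297% (quartiles 0.234% and 1.4%), under the 0.5% this needed, so the prediction failed. HET_early_3 had a higher one at 0.87%. This selection by a median let single other libraries be high, with Myh4 at 1529.9 in HET_early_3, so the HET_early_3 value alone could not decide. Cartilage of the same tumour sample cannot account for the Y-linked reads at 1.87%. Neither explanation covered all the values, and the origin of these reads stays open.

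WT_early_2 and WT_late_3 had low Xist (0.9 and 1.2) and Y-linked levels of 11.4% and 32.4% of the other libraries with low Xist.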
